A study of Drosophila melanogaster with 8 samples.

How the data were processed

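Each of the 8 arrays compared cRNA from pooled heads of treated unmated Oregon-R males with cRNA from the parallel control pool, 4 arrays for each of day 10 and day 14. Per the labels' protocols, RNA was amplified, labelled with Cy3 or Cy5 and hybridised to spotted Drosophila cDNA arrays, which were scanned and quantified with GenePix software. Per the labels, the values are ratios normalized per array in Acuity by the authors, and weak, saturated or irregular spots were filtered out, which leaves blanks in the table. The deposited values are log2 ratios of the 2 channels; base 2 follows from the values themselves, whose extremes equal log2 of 0.001, 0.002 and 100025. Which dye is the numerator, and whether dye-swapped arrays were turned before deposit, is not given in the sources used here. For 3 of the 4 day 14 arrays, the line of the labels on the order of feeding gives ETH, an abbreviation not explained there, for the 3 days of the second drug. These arrays were grouped by their titles, which carry the abbreviation for gabapentin, and the drug they received is open to that extent. Scanner files were not analysed here, so signal over background could not be examined.

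The platform annotation gave 15116 features exactly 1 gene symbol, 102 several and 12430 none. Of the first, 14894 matched the RefSeq gene table through their gene identifier and 222 kept the annotation's symbol. Features with 1 symbol were averaged per gene and array, giving 6793 genes, and all other features were tested under their own number and not named. Each odd-numbered feature and the next appeared to be paired spots, with Spearman correlations of 0.58 to 0.83 against 0.34 to 0.62 for neighbours of different pairs. The other features, 6241 of 11312 tested at day 10 and 3556 of 6142 at day 14, were not averaged over pairs. Counts of genes and features can therefore hold 1 pair as 2 members. Genes spotted from different clones were compared, and Spearman correlations between the clones of 684 genes ran from 0.04 to 0.28 on the 8 arrays. After the centring by position described below they ran from 0.0001 to 0.167.

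Arrays with treated RNA in Cy3 had their sign turned. The moderated test of limma 3.58.1 in R 4.3.3 was fitted to all 8 arrays with a mean for each day, on genes and features with values on at least 3 of the 4 arrays of a day, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The difference between the days was tested as a contrast. Errors are standard errors from this fit. Of 30 gene lists, those with at least 5 measured members were tested against all other named genes with cameraPR at a preset correlation of 0.01, and again with a correlation estimated from residuals. Where arrays were not centred, those residuals held the offsets of whole arrays, which tend to raise the correlation within any list. A call lost there does not separate the list from the offsets. Estimates below 0 were set to 0, so with arrays centred the estimate could be less strict than the preset. The lists were fixed before the data were examined, and 5 genes that name patterns had caught wrongly were removed before any test. The 8 arrays are biological replicates per the labels, and their number limits the precision: the median standard error was 0.299 at day 10 and 0.269 at day 14.

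The groups, tests, alternatives and the rule for named genes were also fixed before the data were examined. That rule took, for each day and direction, up to 10 genes past the threshold with 1 sign on every measured array, filled up to 6 by smallest unadjusted p, then 3 genes per direction for the day difference, 3 members of each list past its threshold, and 12 genes fixed by name, of which 4 had enough values. Alternatives fixed in advance left the swapped arrays unturned, centred arrays on their medians, changed the filter on missing values, tested features alone, added a dye term or a replicate block, used array weights or robust variances, relaxed the threshold, fitted each day alone, took each dye orientation alone, and left out each array. Centring by position, in which medians of runs of 576 and then of 24 features in table order were subtracted, was chosen after seeing the data, as were its combinations with other settings, arrays centred combined with other settings, an estimated correlation without the sign change, and the P450 list without Cyp313 members.

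The fit was tested on simulated data with the real pattern of blanks, the spread of each gene and 200 changed genes. The noise was drawn independently for each gene and array and held no drift along the table, which the real arrays do show. Recovery and false calls in the real data can therefore differ from those below. With no array offsets, it recovered 40% of changes of 1 log2 unit and 75% of changes of 2 log2 units among 11312 genes and features at day 10, with 4 false calls. At day 14, among 6142, it recovered 78% and 98%, with 8 false calls. With the real array offsets kept, day 10 recovery was 26% and 94% with 42 false calls, and day 14 recovery 66% and 100% with 17. Python 3.11.15 with pandas 2.3.3 prepared the tables.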

Results

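Gene expression in heads of Drosophila melanogaster was compared between drug-fed males and males kept on normal food, using spotted cDNA arrays that measure 2 dye-labelled samples at once. The drug-fed flies of the Oregon-R wild type received pentylenetetrazole, a convulsant that blocks GABA-A receptors, at 8 mg/ml for 7 days and then gabapentin, an anticonvulsant, at 16 mg/ml for 3 days. In the day 10 group, heads were taken at that point, and in the day 14 group after 4 further days on normal food. For 3 of the 4 day 14 arrays, 1 line of the labels gives the abbreviation ETH for the 3 days of the second drug, so the drug given to most of that group is open to that extent. Each group held 4 arrays, and each array set the treated heads of 1 biological replicate against its parallel control. Treated RNA carried Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4. The 27648 array features gave between 12929 and 19719 values per array at day 10 and between 6628 and 14095 at day 14. Only 3048 features had a value on all 8 arrays.

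The arrays were not centred on a ratio of 1. Median deposited log2 ratios ran from -0.83 to 0.08 at day 10 and from -0.48 to 0.29 at day 14. The ratios also drifted with the order of features in the table, and medians over 48 consecutive runs of features on day 10 replicate 1 ran from -1.76 to -0.13.

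**Figure D1:**
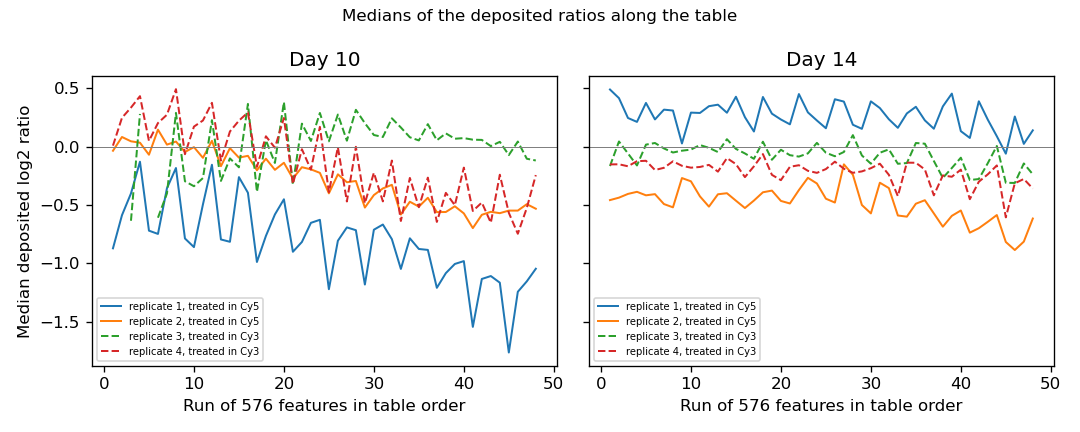
Median deposited log2 ratio (vertical axis) of 48 equal runs of features in table order (horizontal axis) on the day 10 and day 14 arrays, 1 line per array, solid where treated RNA was in Cy5 and dashed where it was in Cy3. On day 10 replicate 1 the medians run from -1.76 to -0.13, and runs with fewer than 20 values are not drawn.

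The direction of the ratios is not settled. The labels give the dyes but not which dye is the numerator, nor whether dye-swapped arrays had been turned before deposit. Values were read as Cy5 over Cy3 and swapped arrays were turned, so that a positive log2 value stands for more signal in treated flies. Deposited means of the Cy5 arrays and the Cy3 arrays correlated across genes and features with a Pearson r of 0.34 at day 10 and -0.05 at day 14, or 0.147 and -0.09 after values were centred by position. Single arrays differed. Day 14 replicate 1 had a Pearson r of -0.27 and -0.10 with replicates 3 and 4, and replicate 2 of 0.19 and 0.18. Day 10 replicate 4 had 0.35 with both replicates 1 and 2, and replicate 3 had 0.03 and 0.02. Centred by position, Spearman correlations were -0.19 and -0.11 for day 14 replicate 1 and 0.09 and 0.04 for replicate 2. At day 10 they ran from 0.07 to 0.12. The day 14 values below 0 thus rested on replicate 1. A treatment effect alone would give a correlation below 0 if the swapped arrays had not been turned and above 0 if they had. Genes are not independent replicates, so no p-value is attached. Directions below hold only for the reading with swapped arrays turned, and 20 of 44 values of named genes changed sign without it.

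The first comparison asked which transcripts differed from control at the end of gabapentin feeding. No single gene passed the test at day 10, while the cytochrome P450 genes, enzymes of drug and hormone metabolism, were lower as a group relative to other named genes. The P450 list had 43 measured members, 29 of which lay below the median of all named genes, and its own median lay 0.12 log2 units below that median (adjusted p = 0.0493, cameraPR with a preset correlation, and adjusted p = 0.99 with an estimated correlation). The call was also lost without the sign change (adjusted p = 0.989), where 24 of 43 members lay below the median and the shift was -0.06. Without day 10 replicate 1 it was lost as well (adjusted p = 0.178), and the shift went from -0.12 to -0.06. It was also lost at a shift of -0.11 with the replicate number as a block (adjusted p = 0.0957), of -0.14 without day 10 replicate 4 (adjusted p = 0.309) and of -0.12 without day 14 replicate 1 or 2 (adjusted p = 0.0514 and 0.057). With arrays centred on their medians it held under both correlations (adjusted p = 0.0194 preset, and adjusted p = 0.00144 with an estimated correlation). The estimated one gave the smaller value, so it was not the stricter test there and adds no separate support. Cyp313a1 had a mean log2 ratio of -0.997 ± 0.28 (SE, n = 4), Cyp310a1 of -1.26 ± 0.38 (SE, n = 4) and Cyp28d1 of -0.80 ± 0.28 (SE, n = 4) with replicate 1 at -1.92 and a mean of -0.42 without it. Cyp310a1 was 0.39 on replicate 3, opposite to the other arrays, and its mean was -0.91 without replicate 1 and -1.82 without replicate 3. Without replicate 1 the mean of Cyp313a1 was -0.70. These 3 genes stood at -0.75, -1.02 and -0.55 relative to the median of all genes and features and -0.66, -0.73 and -0.31 centred by position, and none passed alone. Of the P450 members, 0 passed over all genes tested and 0 when adjusted over the list alone. Markers of glia, with 5 to 13 measured members per array, had a median below the array's median on all 8 arrays (-0.35 to -0.08 with arrays centred). Centred by position, the medians ran from -0.34 to -0.002. They were close to 0 on day 10 replicates 1 and 4 (-0.004 and -0.0035) and on day 14 replicate 3 (-0.002). The glia list was 1 of many, and this pattern over arrays was not tested. The list did not pass at day 10 (shift -0.17, adjusted p = 0.271) or at day 14 (shift -0.11, adjusted p = 0.449). Without the sign change the shifts were -0.19 and 0.12.

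The median of all genes and features tested at day 10 was itself -0.25 and moved to 0.03 when arrays were centred, so the values of these genes are also given relative to it. Among genes with 1 sign on every measured array, the lowest unadjusted p-values belonged to CG1421 with a log2 ratio of -1.88 ± 0.36 (SE, n = 3), which is -1.63 relative to the median, and to CG5966 with -1.21 ± 0.27 (SE, n = 4), which is -0.96 relative to it. CG32236, lky, Gld2 and CG6059 followed at -1.28, -1.42, -1.44 and -1.02, or -1.03, -1.17, -1.19 and -0.77 relative to the median. On the higher side, Alp9, an alkaline phosphatase, had 0.97 ± 0.36 (SE, n = 3) and tefu, a DNA damage kinase, had 0.66 ± 0.25 (SE, n = 4), or 1.22 and 0.91 relative to the median. ATP8A, Rrp1, CG13001 and CG4661 had 0.70, 0.64, 0.70 and 0.62, or 0.95, 0.89, 0.95 and 0.87 relative to it. Centred by position, the 6 lower genes stood at -1.51, -0.77, -0.78, -0.86, -0.89 and -0.52 and the 6 higher at 1.01, 0.66, 0.13, 0.94, 0.95 and 0.92, in the order given. Without replicate 3 ATP8A stood at 0.43, and without replicate 4 CG13001 stood at 0.34. None of these 12 genes passed, with adjusted p-values between 0.552 and 0.772. When limma was fitted to day 10 alone, CG1421 passed (adjusted p = 0.0308). Without the sign change CG1421 stood at -0.02, Alp9 at 0.03, and 4 of the 12 turned, ATP8A, CG13001, CG4661 and CG6059, to -0.13, -0.38, -0.50 and 0.12.

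Genes close to the drugs' known targets did not pass the test at day 10, and their values depended on the array offsets. Gad1, which makes GABA, had 0.09 ± 0.28 (SE, n = 3), the GABA receptor subunit gene Lcch3 had 0.01 ± 0.26 (SE, n = 4), and stj, which encodes an alpha2-delta calcium channel subunit of the kind gabapentin binds in mammals, had -0.08 ± 0.26 (SE, n = 4). The clock gene per had -0.10 ± 0.34 (SE, n = 3). The signs rested on single arrays: without replicate 1 per stood at 0.36, stj at 0.12 and Lcch3 at -0.15, and without replicate 2 Gad1 stood at -0.08 and Lcch3 at -0.05. Relative to the median of all genes and features Gad1, Lcch3, stj and per stood at 0.34, 0.26, 0.17 and 0.15, with arrays centred at 0.42, 0.28, 0.19 and 0.23, and centred by position at 0.18, 0.08, 0.16 and 0.23. The lists of GABA signalling genes and calcium channel subunits had too few measured members for a list test. Of the 27 other lists tested, none passed. The immune response list, with 8 measured members and a median 0.22 below that of named genes, had an adjusted p of 0.0873, as did olfaction and odorant binding, cytosolic ribosomal proteins, and testis and male accessory gland. The immune response shift was -0.08 without replicate 1 and -0.29 without replicate 4. With arrays centred, the immune response list passed (adjusted p = 0.0194), but not without replicate 1 (adjusted p = 0.163) or replicate 4 (adjusted p = 0.381), and too few of its members had values on all 8 arrays for a correlation to be estimated. Over all lists, 0 members passed over all genes tested and 3 when adjusted over the list alone, 1 each in the immune response, muscle and testis lists.

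By limma's moderated test, 0 of 11312 genes and features passed at day 10, and 597 had an unadjusted p under 0.05. Of these, 586 were lower, a share that rests on values with a median of -0.25 and on the direction read from the labels. The 597 became 370 without replicate 1, 1887 without replicate 4, 477 with arrays centred and 2364 without the sign change. Array weights gave 86, and 0 once values were centred by position as well, with 578 at an unadjusted p under 0.05. Deposited signs left as they were on both days gave 57, and the replicate number as a block gave 29 of 6277, all lower. Within 1 dye orientation, where the sign of all arrays is shared, the Cy5 arrays gave 436 and the Cy3 arrays 67, and both counts became 0 after values were centred by position, with 783 and 872 at an unadjusted p under 0.05.

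The second comparison asked which transcripts differed from control after 4 days without drug. The P450 genes and the genes of glycolysis and the TCA cycle were lower as groups at day 14 with a preset correlation between genes but not with an estimated one (adjusted p = 0.000562 preset, and adjusted p = 0.864 with an estimated correlation, for both), and no single gene passed. The P450 list had 25 measured members, 15 below the median of named genes, and a median 0.18 log2 units lower, a shift that was -0.12 without day 14 replicate 1 or replicate 4, where the call held. The glycolysis and TCA list had 17 measured members, 13 below that median, and a median 0.19 lower. With arrays centred, which takes whole-array offsets out of the estimate, both passed with either correlation (adjusted p = 0.000215 and 0.00367 with an estimated correlation). For P450 the preset correlation gave the larger value (cameraPR adjusted p = 0.000947), so the estimated one was not the stricter test there. Without the sign change both medians turned, to 0.02 above that of named genes for P450 and to 0.11 above for glycolysis and the TCA cycle, and 2 other lists passed, both higher, cytosolic ribosomal proteins at 0.21 (adjusted p = 0.0214) and head fat body and lipid metabolism at 0.08 (adjusted p = 0.0281). Neither passed there with an estimated correlation (adjusted p = 0.931 with an estimated correlation, for both). With the sign change the head fat body list had 12 of 17 members below the median and a shift of -0.12, and it did not pass (adjusted p = 0.249). That outcome depended on which arrays were kept: without day 14 replicate 1 the list passed (14 of 17 below, shift -0.16, adjusted p = 0.011).

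Cyp313a1 had a log2 ratio of -0.82 ± 0.26 (SE, n = 4) at day 14, Cyp4d21 of -0.63 ± 0.27 (SE, n = 4), or -0.32 without replicate 2, and Cyp9f2 of -0.63 ± 0.30 (SE, n = 3). Gpdh1, the glycerol-3-phosphate dehydrogenase gene, had -0.49 ± 0.25 (SE, n = 4), or -0.33 without replicate 2. The glycogen phosphorylase gene Glyp had -0.49 ± 0.26 (SE, n = 4), and Scsalpha1, a succinyl-CoA synthetase subunit gene, had -0.43 ± 0.25 (SE, n = 4). Centred by position, these 6 genes stood at -0.82, -0.53, -0.39, -0.25, -0.41 and -0.35, and without the sign change Cyp9f2 turned to 0.10 and Scsalpha1 to 0.06. In both lists 0 members passed over all genes tested and 0 when adjusted over the list alone. The glycolysis and TCA call was lost without day 14 replicate 3, where the shift went from -0.19 to -0.12 (adjusted p = 0.0743), and the P450 call after centring by position (adjusted p = 0.101).

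**Figure D2:**
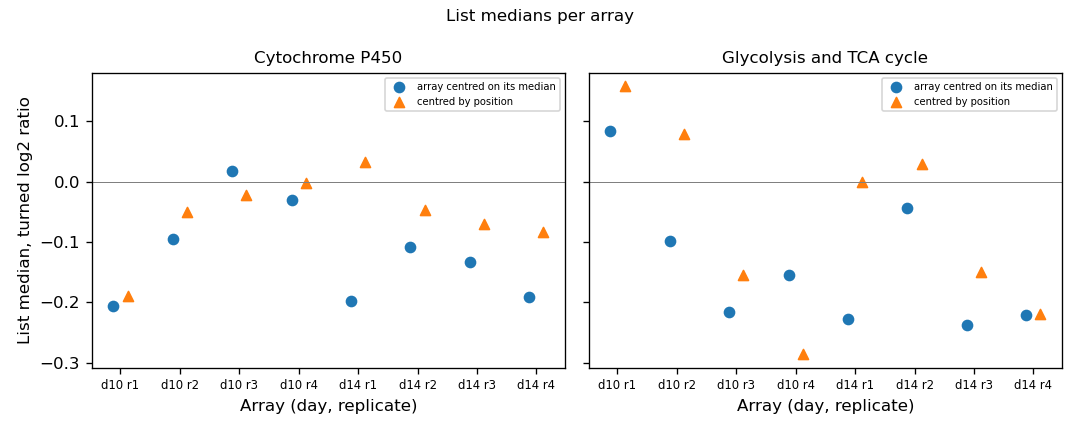
Median turned log2 ratio (vertical axis) of the measured P450 genes and of the glycolysis and TCA cycle genes on each of the 8 arrays (horizontal axis, d for day and r for replicate). Circles are values centred on the array's median and triangles values centred by position in the table. The P450 medians run from -0.21 to 0.02 with arrays centred.

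Other genes at day 14 did not pass either, and their adjusted p-values were all 1. Among genes with 1 sign on every measured array, the lower genes with the smallest unadjusted p-values after Cyp313a1 were CG5946 at -0.76, the growth-blocking peptide gene Gbp2 at -0.75, CG4914 at -0.58, CG7966 at -0.57 and the cytochrome b5-related gene Cyt-b5-r at -0.57. The higher genes chosen in the same way were KrT95D at 0.74, which rested on replicate 2 and was 0.13 without it, CG13898 at 0.70, glec at 0.68, CG10340 at 0.62, Snx17 at 0.59 and the fatty acid synthase gene FASN3 at 0.59. Without the sign change 5 of the 6 higher and 5 of the 6 lower genes turned, all but KrT95D at 0.57 and Cyp313a1 at -0.20, with CG13898 at -0.17 and Gbp2 at 0.30. Centred by position, the 5 lower genes after Cyp313a1 stood at -0.64, -0.40, -0.43, -0.23 and -0.36 and the 6 higher at 0.69, 0.31, 0.38, 0.16, 0.28 and 0.33, in the order given. Gad1 had 0.03 ± 0.25 (SE, n = 4) and stj -0.05 ± 0.29 (SE, n = 3), and their signs turned without 1 array, to -0.06 for Gad1 without replicate 4 and to 0.17 for stj without replicate 2. The 23 other lists had adjusted p-values between 0.139 and 0.932, the smallest for oxidative stress defence.

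At day 14, 0 of 6142 genes and features passed limma's test, and 69 had an unadjusted p under 0.05. That number was 280 with arrays centred, 327 after centring by position, 270 without the sign change, 148 without day 10 replicate 1, and 240, 20 and 21 without day 14 replicates 2, 3 and 4. The replicate number as a block gave 1 call, unnamed feature 6593, which had a turned value of -16.61 on day 14 replicate 4. Array weights gave 1156, with a weight of 6.97 for replicate 3 against 0.27 for replicate 2, and 0 once values were centred by position as well, with 809 at an unadjusted p under 0.05.

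The third comparison asked whether the treated-over-control ratio differed between the days. No gene and no list passed. The antimicrobial peptide gene Drs had the smallest unadjusted p, with -1.31 ± 0.38 (SE, n = 3) at day 10 and 0.13 ± 0.28 (SE, n = 4) at day 14, a difference of 1.44 ± 0.43 (SE; limma adjusted p = 0.936). Without day 14 replicate 1, which stood at 1.43, Drs was at -0.30 at day 14 and the difference was 1.01. The median difference of all genes and features was 0.27, so Drs lay 1.17 above it. The mitochondrial ribosomal gene mRpS34 differed by 1.08 and CG31793 by 1.07. Without day 14 replicate 1 these differences were 0.75 and 0.87, and the day 14 mean of mRpS34 went from 0.14 to -0.18. On the lower side stood tefu at -0.79, the cytochrome c oxidase gene COX4 at -0.62 and CG13933 at -0.66, and without day 14 replicate 2 tefu was at -0.49 and CG13933 at -0.39, and without day 10 replicate 3 CG13933 was at -0.40. Centred by position, Drs, mRpS34 and CG31793 differed by 1.09, 0.45 and 0.44, and tefu, COX4 and CG13933 by -0.72, -0.43 and -0.41. Without the sign change CG31793 turned to -0.27, COX4 to 0.29 and CG13933 to 0.15. Limma gave 0 of 5187 genes and features past the threshold, 112 with an unadjusted p under 0.05, 670 with array weights and 1, unnamed feature 6593, with the replicate number as a block. The 112 became 598 without day 10 replicate 4, 448 without day 14 replicate 2 and 220 centred by position. They became 50 without day 10 replicate 1, and 47, 60 and 47 without day 14 replicates 1, 3 and 4. Array weights gave 0 once values were centred by position as well, with 330 at an unadjusted p under 0.05. Leaving out day 10 replicate 4 gave 11. Of the 23 lists measured on both days, 0 passed.

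Mean log2 ratios of the 2 days correlated across 5187 genes and features with a Pearson r of 0.21 and a Spearman rho of 0.21. The days had separate controls, and genes are not independent replicates. Without day 10 replicate 4 the Pearson r was 0.08.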

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

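The tests of position, dye, earlier turning, array medians, single arrays with arrays centred or centred by position, and Cyp313 members, and the counts over other sign patterns and splits, were chosen after the data were seen.

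Of 38 sets of 4 arrays examined, 4 held an array apart from the rest by the ratio of its gap to the range, where chance gives about 1 in 20. Day 10 replicate 3 had 12929 features with a value against 18579 or more on the other day 10 arrays (ratio 0.832). The glycolysis and TCA cycle median on day 14 replicate 2 was -0.04 against -0.24 to -0.22 on the others (ratio 0.910). COX4 at day 14 was 0.26 on replicate 1 and -0.40 to -0.33 on the others (ratio 0.893). Cyp28d1 at day 10 was -1.92 on replicate 1 and -0.57 to -0.34 on the others (ratio 0.851). Both gene flags used turned values with the array offsets kept. Replicate 1 had the highest array median at day 14 (0.29) and the lowest at day 10 (-0.83). Offsets of whole arrays may therefore account for both gene flags, which were not examined with arrays centred. Snx17 had opposite signs on every measured array of the 2 days, with a difference of 0.788, and by limma it did not pass (adjusted p = 0.936). With arrays centred its day 10 mean was 0.07 and the difference 0.345.

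With swapped arrays turned, the P450 list was lower on both days at the preset correlation, and with arrays as deposited neither call held with an estimated one (adjusted p = 0.99 at day 10 and 0.864 at day 14 with an estimated correlation). Centring by position left the day 10 shift at -0.12 and the list past the threshold (adjusted p = 0.017), which argues against position, as far as this centring removes it, as the whole cause there, though the call ended without replicate 1, 3 or 4 (adjusted p = 0.0602, 0.0858 and 0.0566, at shifts of -0.07, -0.11 and -0.09) and may rest on single arrays, while at day 14 the shift went from -0.18 to -0.03 and the call ended (adjusted p = 0.101), so position may account for that part. With arrays centred, leaving out 1 array ended the day 10 call for replicate 1, where the shift fell from -0.11 to -0.06 (adjusted p = 0.182), and for replicate 4, where it was -0.13 (adjusted p = 0.213), whereas the day 14 call held for each of its 4 arrays (highest adjusted p 0.0138), with the shift going from -0.15 to -0.10 without replicate 4. Without the 3 Cyp313 members measured at day 10, which could share signal, the shift was -0.10 against -0.12 and the call ended (adjusted p = 0.0873), and at day 14 only 1 was measured, so leaving it out (adjusted p = 0.00595) tests nothing about shared signal. An effect of the drugs remains open and untested, and an earlier turning of the ratios remains open.

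With swapped arrays turned, the glycolysis and TCA cycle list was lower at day 14 at the preset correlation with a shift of -0.19, and not with an estimated one (adjusted p = 0.864 with an estimated correlation). After centring by position the shift was -0.12, which passed at the preset correlation (adjusted p = 0.012) and not with an estimated one (adjusted p = 0.52 with an estimated correlation), so position may account for part of it, and with arrays centred the list passed without each array of the day in turn (highest adjusted p 0.0011), with the shift going from -0.21 to -0.12 without replicate 4. After centring by position the call ended without replicate 3 (adjusted p = 0.141) and without replicate 4 (adjusted p = 0.151), where the shift went to -0.09 and -0.06, so a dependence on 1 array may remain there. If the ratios were not turned before deposit, a dye effect cancels in the turned mean of both orientations, and over the 13 members with values on all 4 arrays the list was lower (adjusted p = 0.00153). That fit did not centre the arrays. Centred by position, the day 14 list medians were 0 and 0.03 on the Cy5 arrays and -0.15 and -0.22 on the Cy3 arrays. At day 10 they were 0.16 and 0.08 against -0.16 and -0.29. After this centring the day 14 shift thus lay on the Cy3 arrays, so a part of dye orientation is not excluded. With arrays centred on their medians, all day 14 list medians were below 0 (-0.24 to -0.04). Ratios turned before deposit cannot be told apart from a treatment effect, since the labels do not state it: without the sign change the list was higher at day 14 and day 10 centred by position (adjusted p = 0.0394 and 0.000133), but did not pass with day 14 alone left unturned (adjusted p = 0.0694), as deposited (adjusted p = 0.129 and 0.505) or with arrays centred (adjusted p = 0.33 and 0.564).

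Day 10 held more small p-values without the sign change than with it. As deposited, 2226 had an unadjusted p under 0.05 with both swapped day 10 arrays unturned and day 14 turned, and more, 2297, with replicate 4 alone unturned, against 597 under the labelled pattern, so the excess over every other pattern held only after centring. With arrays centred, 2442 genes and features had an unadjusted p under 0.05 against at most 2034 under the 7 other sign patterns, and after centring by position 1219 against at most 743. So neither array medians nor position, as far as this centring removed it, alone accounted for the excess. Neighbouring features of different pairs still correlated at 0.07 to 0.16 on the day 10 arrays after it, so position is not excluded. Swapped and unswapped day 10 arrays had a mean Spearman correlation of 0.0865 after centring by position. Ratios turned before deposit and a dye effect per gene would both give this, as could position left after centring, and these cannot be told apart here.

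The 8 sign patterns of a day's 4 arrays are too few for a share under 0.05. At day 10 the labelled pattern gave 0 genes, a number that all 8 patterns reach whatever the values, and the highest other gave 83, with the day 10 swaps left unturned and day 14 turned, where leaving both days unturned gave 57. It gave 1 list, reached by 2 patterns, with 1 the highest other. At day 14 it gave 0 genes, again reached by all 8 patterns, with 2 the highest other, and 2 lists, reached by 4 patterns, with 5 the highest other. For the difference between the days the real split gave 0 genes, which all 35 splits of the 8 arrays reach whatever the values, so that count tests nothing about chance. The highest other split gave 2018 and set day 10 replicates 1 to 3 with day 14 replicate 2 against the rest, and it gave 0 with arrays centred, so offsets of whole arrays set that count. The split by dye orientation gave 283, 34 with arrays centred and 55 centred by position, and with either centring every other of the 35 splits gave 0. On turned values this split tests the deposited ratios of both days without the sign change. Ratios turned before deposit and a dye effect per gene would both give such calls, so the split does not tell them apart.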

How the results depend on the processing

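Centring by position, pairs of settings and the P450 list without Cyp313 members were chosen after seeing the data; the others were planned. Causes were not tested except where stated, and scanner signal over background was not analysed here. Day 10 changed genes numbered 0, and 57 with no sign change, 12 with a dye term, 86 with array weights, 436 on Cy5 arrays alone, 67 on Cy3 arrays alone and 3 with that day alone, and 0 without each array. Day 14 changed genes numbered 0, and 1 with no sign change (CG1806), 1 when measured on all 4 arrays, 2 with a dye term, 1156 with array weights, 15 on Cy3 arrays alone, 2 with that day alone, 3 with arrays centred and no sign change, and 0 to 1 without an array. The single call on all 4 arrays and without an array was unnamed feature 6593, with a value of -16.61 on day 14 replicate 4. The difference between the days numbered 0, and 2 with a dye term, 670 with array weights, 15 on Cy3 arrays alone and 0 to 11 without an array. Counts stayed at 0 in all 3 comparisons with arrays centred, with centring by position, with each feature alone, with robust variances and at an adjusted p under 0.10.

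The correlation of the days was 0.206, and 0.285 with no sign change, 0.292 on genes measured on all 8 arrays and 0.0824 to 0.261 without an array. Lists past the threshold at day 10 numbered 1, and 0 with no sign change, 2 with arrays centred (P450 and immune response), 0 when measured on all 4 arrays, 2 with position centring and no sign change (glycolysis and TCA cycle, and olfaction and odorant binding), 0 with arrays centred and no sign change, 0 with an estimated correlation, also with no sign change, and 0 to 2 without an array. At day 14 they numbered 2, and 2 others with no sign change (cytosolic ribosomal proteins, and head fat body and lipid metabolism), 1 with position centring and 1 with position centring and no sign change (glycolysis and TCA cycle in both), 1 with arrays centred and no sign change (cytosolic ribosomal proteins), 0 with an estimated correlation, also with no sign change, 0 with position centring and an estimated correlation and 1 to 3 without an array. With no sign change the day 14 shift turned for P450 (0.0239, or 0.0434 centred by position and 0.0155 with arrays centred) and for glycolysis and the TCA cycle (0.107, or 0.0968 and 0.128). Of 44 values of named genes, 20 changed sign with no sign change of the arrays and 3 with arrays centred.

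Whether the replicate numbers pair the arrays is open: deviations of same-numbered arrays correlated at 0.03, 0.37, 0.22 and 0.19 for numbers 1 to 4 across 2217 genes and features, and at 0.149, 0.251, 0.209 and 0.135 after centring by position, and numbers 1 and 4 correlated better with another number, 2 and 3. Same-numbered arrays shared their dye orientation on both days, and each best match lay within 1 orientation. Dye orientation alone could therefore give these correlations. With the number as a replicate block, which also takes up the dye orientation, counts were 29 at day 10, 1 at day 14 and 1 for the difference, over fewer genes tested, 0 lists passed at day 10, and both list calls at day 14 stayed past the threshold. The single calls at day 14 and for the difference were unnamed feature 6593.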

Other observations

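Arrays with treated RNA in Cy3 resembled each other across days. After centring by position, which was chosen after seeing the data, Spearman correlations of deposited ratios between a day 10 and a day 14 array averaged 0.172 over the 4 pairs with treated RNA in Cy3 and 0.0314 over the 4 pairs with it in Cy5, against 0.0078 over 8 pairs with opposite dyes.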
